A study of Homo sapiens with 3 samples.

How the data were processed

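The series held 3 droplet single-cell RNA libraries made with 10x Genomics Chromium chemistry and read on a NovaSeq instrument, per the labels' protocols. All came from H1, an established human embryonic stem cell line, differentiated toward pancreatic beta cells. 1 library was unedited (WT), another was labelled heterozygous for a PAX6 lesion (HET) and the last homozygous (KO). The position of the lesion in PAX6 and whether the kit read the 3′ or the 5′ end are not given in the sources used here. Each genotype had 1 library, so genotype and library are the same thing in every comparison. No p-value or standard error is given for any difference between genotypes, and no difference has a replicate check.

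The deposited values were raw UMI counts, stored as whole numbers per gene and barcode in 1 matrix per library. They were written by Cell Ranger 6.1.2, per the file headers. The submitters' processing notes name GRCh38 and Seurat without a version or a role. The annotation release, the aligner settings and any filter on barcodes are not given in the sources used here. Every barcode had at least 500 UMIs in each deposited file. Each matrix had 33538 genes, of which 33456 were found by identifier in GENCODE 29, and 33071 of these carried the same symbol. Coordinates are those of GENCODE 29 on GRCh38. INS overlaps the INS-IGF2 readthrough gene and PRSS1 and PRSS2 are near-identical paralogs, so their counts depend on how reads were assigned.

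Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrially encoded genes. Doublets were scored in each library with Scrublet (in scanpy 1.11.5; expected rate 0.08, automatic threshold) and those called were removed. The automatic threshold called 751 WT barcodes (8.67%) and none of the 8468 HET or 8785 KO barcodes. The caller therefore did not work in HET and KO, whose cells still include doublets. An alternative chosen after seeing the data removed the top 8% of scores from each library, and several of its values are printed beside the main ones. After filtering, 7911 WT, 8468 HET and 8785 KO cells remained.

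Cells of the 3 libraries were clustered together without batch integration, since library and genotype coincide. PAX6, the mitochondrial and ribosomal protein genes and 4 gene lists (islet hormones and the IRE1-XBP1, PERK-ATF4 and ATF6 branches of the unfolded protein response) were left out of the 2000 variable genes. Clustering used 30 principal components, a shared-neighbour graph of 20 neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), which gave 19 clusters. A cluster was called endocrine-like when at least 10 of 19 endocrine markers were at least 2-fold above all other cells. The number of markers needed was chosen after seeing the data. Any number from 1 to 15 would have given the same split, because the 7 clusters that passed had 15 to 18 such markers and the other 12 had 0. The marker lists of single islet cell types did not enter this rule. A cluster was called beta-like when at least 3 beta markers, and more than those of any other class, were among its 10 leading genes. The names were rebuilt from markers and may differ from those of the study.

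Counts were summed per library over the cells of a class and scaled to CPM, counts relative to the library total, with TMM factors from edgeR 4.0.16 (R 4.3.3), computed on the 3 sums. Levels have exact Poisson intervals and shares have exact (Clopper-Pearson) binomial intervals, all at 95%. These cover counting error only, not variation between differentiations or libraries. A gene at 0 was set against a floor of 3 counts in that library. For counts of genes, a gene needed at least 50 CPM in 1 of the libraries compared and at least a 2-fold difference. The named genes were the 10 highest and the 10 lowest by log2 ratio among these in KO against WT and in HET against WT, with mitochondrial, ribosomal protein and sex-linked marker genes and unnamed clones left out. Members of gene lists with at least 5 CPM in a library could be named as examples, with PAX6, ERN1, XBP1, INS, GCG, SST, GHRL and IAPP always among them.

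The groups, the markers, the comparisons, the rule for named genes, the other main settings and the 28 gene lists were fixed before the data were examined. The lists were islet hormones, beta cell transcription factors, transcription factors of other islet cells, hormone processing and granule genes, glucose sensing, exocytosis, the 3 unfolded protein response branches, apoptosis and p53 genes, cell cycle, progenitor and duct genes, genes normally kept low in islets, enterochromaffin genes, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, immediate early and dissociation genes, cholesterol synthesis, neuronal genes, interferon and antigen presentation genes, and markers of mesenchymal, endothelial, liver, intestinal, acinar, pluripotent and immune cells. For each list, the median log2 ratio of its measured members (count prior 0.5) is given with an interval from 2000 bootstrap draws of its members. Its percentile among 10000 random lists of the same size, matched on expression in 20 bins, describes these libraries and is not a test of genotype. The code was tested on simulated data drawn from the real means and depths, with 200 genes changed. In the KO and WT endocrine-like sums (3392 genes), genes set 2-fold higher were recovered at a median log2 of 0.99 and genes set 4-fold higher at 2.01. None of the unchanged genes reached 2-fold.

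Shares of cells with a hormone UMI were taken after thinning each cell to 2000 UMIs, and are also given without thinning. Alternatives chosen beforehand covered scaling (plain CPM, median-of-ratios factors with DESeq2 1.42.0, and totals without hormone and mitochondrial genes), expression minimums, cell filters, doublets, weighting of cells, clustering and depth. Removing the top 8% of doublet scores, leaving out the low-UMI endocrine-like cluster, weighing equally the clusters with at least 20 cells in every library (14 to 18, or 1 to 11 for non-endocrine cells) and centring ratios on transcript length were added after seeing the data. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.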

Results

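Single-cell RNA profiles were collected from beta cell differentiations of the H1 human embryonic stem cell line in 3 PAX6 genotypes, unedited (WT), heterozygous (HET) and homozygous (KO), with 1 library each. PAX6 is a transcription factor of the developing eye, brain and pancreatic islet. The WT library held 9667 barcodes and 140068492 UMIs, the HET library 9628 barcodes and 136834433, and the KO library 9726 barcodes and 145948590. The median barcode had 13571, 13111 and 14365.5 UMIs. With 1 library per genotype no difference below could be tested against variation between differentiations. Intervals of levels, ratios and shares cover counting error only, and those of list medians cover the spread between list members.

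PAX6 itself (chromosome 11, 31784779 to 31818062, minus strand) was still present as RNA in the KO library. In endocrine-like cells its level was 383 CPM in WT (374 to 392), 240.3 CPM in HET and 282 CPM in KO. It was 1.36-fold lower in KO (1.31 to 1.41) and 1.59-fold lower in HET (1.52 to 1.67) than in WT. Non-endocrine cells held 4.35, 2.97 and 2.05 CPM of PAX6 in the same order. The place of the lesion is not in the labels, and an edited allele can still be transcribed, so these counts do not check the genotype. The order also depended on which endocrine-like cells were counted. With clusters 14 to 18 weighing the same, a setting added after seeing the data that leaves out cluster 13 for its few KO cells, the log2 ratio to WT was 0.87 for KO and 0.23 for HET, in place of -0.44 and -0.67. It was -0.21 and -0.33 with the top 8% of doublet scores removed from each library.

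Endocrine-like cells, named for chromogranins, secretogranins and islet transcription factors, made up 18.7% of the kept WT cells (17.8 to 19.5), 7.32% of HET cells (6.78 to 7.90) and 13.1% of KO cells (12.4 to 13.8). The HET and KO shares were 6.69% and 12.4% with the top 8% of doublet scores removed from each library, and the 3 shares were 16.1%, 5.54% and 8.09% when cells needed at least 3000 UMIs and at most 10% mitochondrial UMIs. This was 1476, 620 and 1152 cells with 18511283, 9661444 and 16080894 UMIs. Their median mitochondrial share of UMIs, a sign of RNA quality, was 6.33%, 8.44% and 8.93% (non-endocrine cells 4.76%, 6.23% and 5.42%), so it changed together with genotype. With the stricter filter just named, the medians for KO and HET against WT were -3.55 and -1.05 for islet hormones and -0.37 and -0.20 for IRE1-XBP1 genes, in place of -3.41, -1.09, -0.44 and -0.22. The 7 clusters of the class were held in different proportions. Cluster 13, led by the hormone genes GCG, PYY, PPY, IAPP and INS, held 39.2% of WT and 27.1% of HET endocrine-like cells but 2 of the 1152 KO cells. Cluster 15, led by the ghrelin gene GHRL and by CRH, held 2.57% of WT, 20.3% of HET and 35.2% of KO endocrine-like cells. Cluster 14, led by TPH1, SCG2 and CHGA, held 17.3%, 16.8% and 27.6%. Cluster 17, led by LINC00682, PHOX2A, TLX2 and CHRNA3, held 6.91%, 11.8% and 17.2%. Of its 10 leading genes only GC, PCSK2 and SCG2 were on a marker list, so the class may include cells that are not of an islet type. The beta-like cluster 18 held 12.0%, 8.71% and 3.99%. Genes used in the clustering, such as TPH1 and SLC30A8, themselves differed between the libraries, and a cluster mostly of 1 library can be that library, so these sizes are given as values and not compared.

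**Figure D1:**
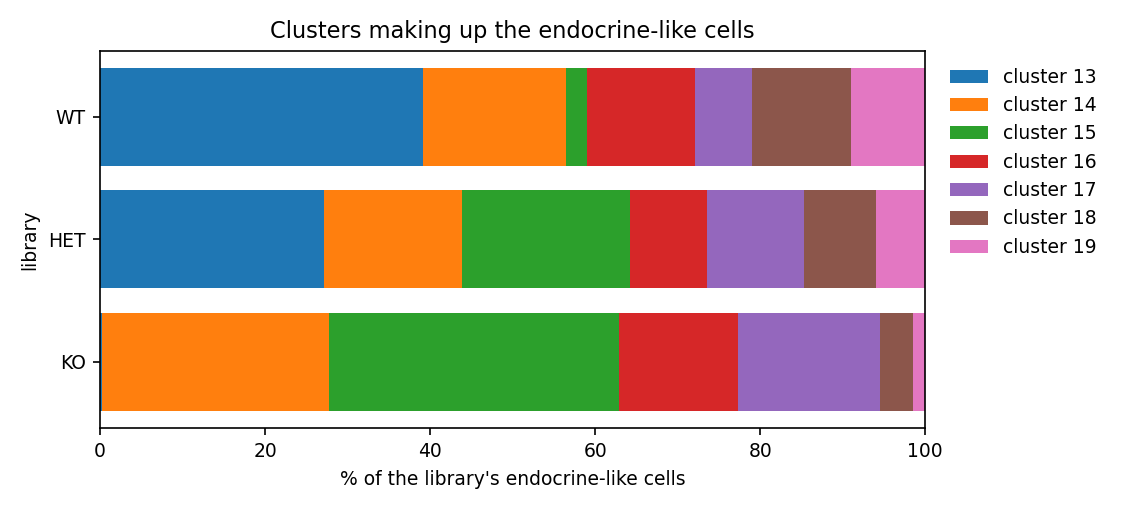
Share of each library's endocrine-like cells (percent, x axis) in each of the 7 endocrine-like clusters, as 1 stacked bar for each of WT, HET and KO (y axis). Cluster 13 holds 39.2% of WT and 0.174% of KO endocrine-like cells, and cluster 15 holds 2.57% and 35.2%.

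In KO against WT, the RNA of most islet hormones was lower in endocrine-like cells and that of ghrelin was higher. GCG, which encodes the alpha cell hormone glucagon (chromosome 2, 162142873 to 162152404), was 35820 CPM in WT and 735 CPM in KO, 48.7-fold lower (47.9 to 49.6). SST, the somatostatin gene of delta cells (chromosome 3, 187668906 to 187670399), was 74.1-fold lower (70.4 to 77.9), PPY 36.7-fold lower (33.4 to 40.5) and PYY 24.3-fold lower (23.3 to 25.3). INS, the insulin gene (chromosome 11, 2159779 to 2161341), was 9138 CPM in WT and 1687 CPM in KO, 5.42-fold lower (5.35 to 5.49). IAPP, which encodes the peptide stored with insulin (chromosome 12, 21354959 to 21379978), had 5990 counts in WT and 1 count in KO, a ratio of 5670 with a counting interval of 1017 to 223970. GHRL (chromosome 3, 10285675 to 10292947) was 655 CPM in WT and 3654 CPM in KO, 5.58-fold higher (5.47 to 5.69). Of 12 hormone genes measured, 9 were at least 2-fold lower, 1 was at least 2-fold higher and 2, GAL and TAC1, lay within 2-fold. The list's median log2 ratio was -3.41 (-5.40 to -1.34), below all 10000 matched random lists. The largest part of the class was cluster 13 in WT, and clusters 15 and 14 together held most of it in KO. With clusters weighing the same, the log2 ratio of GHRL was -0.28 in place of 2.48, that of INS -1.19 in place of -2.44, that of GCG -3.00 in place of -5.61 and that of PYY -2.60 in place of -4.60. The equal-weight value of GHRL was set by cluster 15 (17085 CPM in WT and 9806 CPM in KO). GHRL was higher in KO in clusters 14 (3.12-fold), 16 (43.7-fold), 17 (7.20-fold) and 18 (1.31-fold). Cluster 16 was the low-UMI endocrine-like cluster, with a median of 2502 UMIs per cell. In cluster 18, 3 of 177 WT and 0 of 46 KO cells had at least 5 GHRL UMIs before thinning. Free RNA was not subtracted, and GHRL in non-endocrine cells was 3.53 CPM in WT and 21.8 CPM in KO. The log2 ratio of PPY was -6.55 in place of -5.20 with the top 8% of doublet scores removed.

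**Figure D2:**
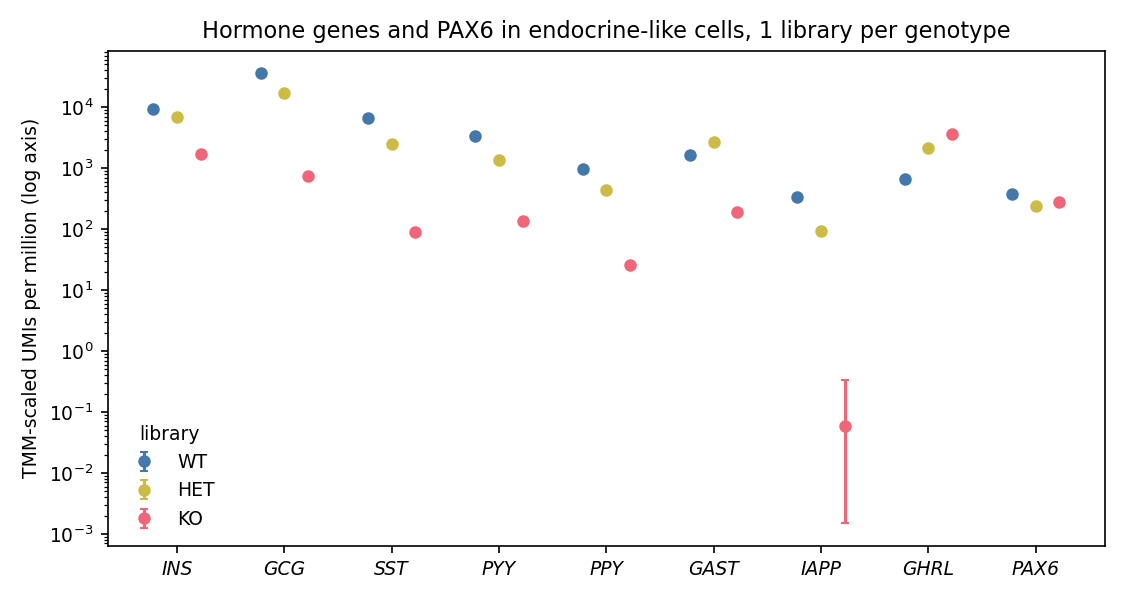
Levels of 8 hormone genes and PAX6 (x axis) in the endocrine-like cells of the WT, HET and KO libraries (TMM-scaled CPM, log y axis), with exact Poisson 95% intervals that cover counting error only and are mostly smaller than the points. GCG lies at 35820 CPM in WT and 735 CPM in KO, GHRL at 655 and 3654 CPM, and the KO point of IAPP rests on 1 count.

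Across 3715 genes with at least 50 CPM, 57 were at least 2-fold higher and 114 at least 2-fold lower in the KO library's endocrine-like cells. The highest ratio belonged to CRH, which encodes the neuropeptide corticotropin-releasing hormone, at 64.7 CPM in WT and 654 CPM in KO (10.1-fold higher). TPH1, the first enzyme of serotonin synthesis outside the brain, was 4.06-fold higher at 453 CPM. The other genes with the largest ratios upward were GHRL, the immediate early gene FOSB (5.37-fold), TNP1 (4.25-fold), the matrix glycoprotein gene THBS1 (3.36-fold), the apolipoprotein gene APOB (3.21-fold), NRP2 (3.10-fold), the metalloprotease gene ADAM12 (3.08-fold) and the fatty acid CoA ligase gene ACSL1 (2.87-fold). Downward, the largest ratios after IAPP were those of FFAR1, the free fatty acid receptor of beta cells, with 1331 counts in WT and 2 in KO (ratio 630, counting interval 174 to 5207), and SLC30A8, the zinc transporter of insulin granules, at 438 CPM in WT and 3.63 CPM in KO (121-fold lower). SST, GCG, PPY and PYY followed, together with LMO2 (262 CPM in WT and 10.1 CPM in KO) and NKAIN4 (148 and 5.71 CPM) and the leukotriene receptor gene CYSLTR2 (18.4-fold lower). With the top 8% of doublet scores removed from each library, APOB (log2 0.48) and NRP2 (-0.21) were no longer 2-fold higher, while the other 18 named genes still were 2-fold apart. GHRL (log2 -0.28), ACSL1 (-0.64) and ADAM12 (0.95) were not 2-fold higher, and 62 genes in place of 114 were 2-fold lower, with clusters weighing the same. Plain CPM moved the median of all genes from -0.02 to 0.12 and the share of lower genes among those 2-fold apart from 66.7% to 49.1%.

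Some genes of granule content and glucose sensing were also lower in the KO library. Of 17 hormone processing and granule genes, 3 were at least 2-fold lower, none was higher and 14 lay within 2-fold. Their median log2 ratio was -0.59 (-0.90 to -0.22, percentile 0). It was -0.34 with the top 8% of doublet scores removed and -0.43 with clusters 14 to 18 weighing the same. SCG5, the chaperone of the prohormone convertase PC2, was 5.40-fold lower and SCG3 2.41-fold lower, whereas the convertase genes PCSK1 (130 and 139 CPM) and PCSK2 (196 and 202 CPM) were near their WT levels. Among 17 glucose sensing genes, 6 were at least 2-fold lower, including the potassium channel subunit gene KCNJ11 (2.37-fold) and the cation channel gene TRPM5 (7.43-fold), and the glucose transporter gene SLC2A1 was 2.97-fold higher. G6PC2, an islet glucose-6-phosphatase, had 180 counts in WT and 0 in KO, at least 56.8-fold lower. The median was -0.68 (-1.32 to 0.31, percentile 0), the same with G6PC2 at that bound, and -0.44 with the top 8% removed. The 18 exocytosis genes had a median of -0.18 (0.08 with the top 8% of doublet scores removed), with 1 higher (BAIAP3), 1 lower (SYT7) and 16 within 2-fold.

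Islet transcription factors went both ways. Of 17 beta cell factors, GLIS3 was 2.09-fold higher in the KO library, none was 2-fold lower and 16 lay within 2-fold, among them PDX1 (149 CPM in WT and 76.5 CPM in KO) and NKX6-1 (85.0 and 81.0 CPM). Their median was 0.06. Of 10 factors of other islet cells, 5 were at least 2-fold lower, including IRX1 and IRX2 of alpha cells (3.46-fold and 2.01-fold), HHEX of delta cells (2.42-fold) and the endocrine progenitor factor NEUROG3 (3.10-fold), and POU3F4 was 2.98-fold higher. The median was -0.91 (-1.40 to 0.20), and -0.19 with clusters 14 to 18 weighing the same. Enterochromaffin genes, of the serotonin cells of the gut, had a median of 0.71 (0.39 to 1.53, percentile 100). Of 12, 4 were at least 2-fold higher, among them TPH1, the vesicular transporter gene SLC18A1 (4.09-fold) and MME (3.63-fold), and 2 were lower, SLC6A4 (14.8-fold) and GCH1 (2.43-fold).

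The series title names the IRE1α pathway, so the 3 branches of the unfolded protein response were examined next. IRE1α, encoded by ERN1 (chromosome 17, 64039142 to 64130819), splices the mRNA of XBP1 (chromosome 22, 28794555 to 28800597), whose protein raises genes of secretion and of endoplasmic reticulum folding. In endocrine-like cells ERN1 was 29.1 CPM in WT, 14.9 CPM in HET and 17.2 CPM in KO, and XBP1 was 261, 221 and 177 CPM. ERN1 was 1.69-fold lower in KO (1.46 to 1.96), XBP1 1.48-fold (1.41 to 1.55) and the cochaperone gene DNAJB9 1.61-fold (1.49 to 1.73). With clusters 14 to 18 weighing the same, the log2 ratio of ERN1 was -0.40 in place of -0.76. That of XBP1 was -0.38 in place of -0.56. That setting leaves out cluster 13, where ERN1 was 37.6 CPM in WT. Of 30 IRE1-XBP1 genes, 27 were lower in KO than in WT, but only KDELR3, a receptor that returns proteins to the endoplasmic reticulum, was more than 2-fold lower (2.92-fold). Their median was -0.44 (-0.57 to -0.21, percentile 0), or -0.27 with clusters 14 to 18 weighing the same. SEC61G, SEC62 and DNAJB11 were the 3 genes higher in KO. The same list had a median of -0.29 (-0.37 to -0.16) in the KO library's non-endocrine cells (-0.25 with their clusters 1 to 11 weighing the same), where PAX6 was at most 4.35 CPM in any library. The difference between the classes, taken gene by gene, had a median of -0.17 (-0.24 to 0.02). Splicing of XBP1 cannot be read from counts per gene.

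ATF6 branch genes, mostly chaperones, had a median of -0.20 in KO against WT (-0.36 to -0.10, percentile 7.11), which was -0.07 with plain CPM and -0.02 with clusters weighing the same. Of 19, 1 was at least 2-fold lower, the oxidoreductase gene ERO1B (10.2-fold), and the chaperone gene HSPA5 was 522 CPM in WT and 456 CPM in KO. The 21 PERK-ATF4 genes had a median of 0.26 (-0.05 to 0.50, percentile 99.7), with SLC7A11, ATF3 and PSAT1 at least 2-fold higher and 18 within 2-fold. ATF4 was 188 CPM in WT and 205 CPM in KO, and the proapoptotic factor gene DDIT3 50.5 and 38.8 CPM. The median lay below 0 when doublets were treated alike in the libraries. Its median was -0.23 with the top 8% of doublet scores removed from each library and -0.14 with doublets kept.

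**Figure D3:**
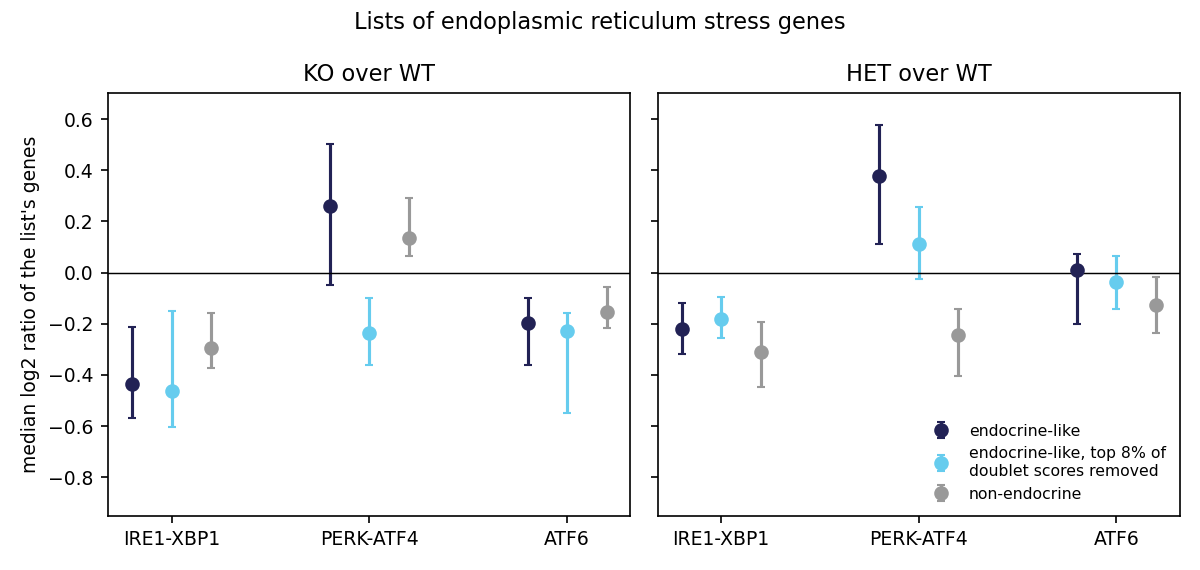
Median log2 ratio to WT (y axis) of the IRE1-XBP1, PERK-ATF4 and ATF6 gene lists (x axis) for KO and for HET, in endocrine-like cells, in endocrine-like cells with the top 8% of doublet scores removed from each library and in non-endocrine cells, with bootstrap 95% intervals over list members. The IRE1-XBP1 medians lie below 0 in endocrine-like cells (-0.44 and -0.22) and in non-endocrine cells (-0.29 and -0.31), and the KO median of PERK-ATF4 genes lies at 0.26 or, with the top 8% removed, at -0.23.

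In HET against WT, islet hormones were lower by smaller factors and ghrelin was again higher. GCG was 17117 CPM in HET, 2.09-fold lower than in WT (2.08 to 2.10), SST was 2.75-fold lower, PYY 2.44-fold, PPY 2.16-fold and IAPP 3.69-fold (3.44 to 3.97). INS was 6937 CPM, 1.32-fold lower (1.31 to 1.33), and GHRL was 2098 CPM, 3.21-fold higher. GAST, which encodes gastrin, was 2726 CPM in HET, 1620 CPM in WT and 189 CPM in KO. Of 12 hormone genes, 7 were at least 2-fold lower, 1 was at least 2-fold higher and 4 lay within 2-fold (median -1.09, -1.67 to -0.23, percentile 0). Cluster 13 was the largest endocrine-like cluster in both libraries. With clusters weighing the same, the log2 ratio of GHRL was -0.54 and that of INS 0.14. That of GCG was -0.56 in place of -1.07, under 2-fold, and it was -0.74 with the top 8% of doublet scores removed. The log2 ratio of INS was -0.10 in place of -0.40, and that of SST -2.76 in place of -1.46, with the same cells removed. Cluster 15 (17085 CPM in WT and 9490 CPM in HET) set the equal-weight value of GHRL. In clusters 14 (1.77-fold), 16 (21.3-fold, the low-UMI cluster), 17 (1.14-fold) and 18 (5.75-fold) GHRL was higher in HET. Free RNA was not subtracted, and GHRL in non-endocrine cells was 3.53 CPM in WT and 35.6 CPM in HET.

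Of 3663 genes, 53 were at least 2-fold higher and 54 at least 2-fold lower in the HET library's endocrine-like cells. FOSB was 9.46-fold higher (8.30 to 10.8). It was also higher in non-endocrine cells, at 33.0 CPM in WT, 108 CPM in HET and 77.2 CPM in KO. CRH was 5.60-fold higher, the motilin gene MLN 4.51-fold, the osteopontin gene SPP1 5.22-fold and LTBP1 4.96-fold. The cadherin gene CDH6 was 3.83-fold higher, the smooth muscle gene TAGLN 3.76-fold, FILIP1L 3.47-fold and ANKRD1 3.19-fold. The largest ratios downward were those of the trypsinogen gene PRSS2 (5.64-fold), the phospholipase gene PLCG2 (4.59-fold), the homeobox gene HOXB2 (3.86-fold), IAPP, LMO2 (3.61-fold), the enkephalin precursor gene PENK (59.0 CPM in WT and 16.4 CPM in HET), STMN4 (3.44-fold), the calretinin gene CALB2 (3.38-fold), SMIM32 (3.27-fold) and NKAIN4 (3.23-fold). Both counts depended on doublets and were 17 higher and 34 lower with doublets kept, while 85 were higher with the stricter filter. With the top 8% of doublet scores removed from each library, 24 genes were 2-fold higher, and SPP1 (log2 0.87), LTBP1 (0.62), CDH6 (0.98), FILIP1L (0.33), ANKRD1 (-0.03) and TAGLN (-0.24) were not among them, while all 10 named lower genes still were 2-fold lower.

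Most granule and exocytosis genes were below WT in the HET library, nearly all by less than 2-fold. All 17 granule genes were below WT, with SLC30A8 at least 2-fold lower (2.61-fold) and a median of -0.55 (-0.73 to -0.39, percentile 0). Of 17 exocytosis genes, 15 were lower and none passed 2-fold, with SYT1 at 38.2 CPM in WT and 19.7 CPM in HET and SNAP25 at 75.3 and 42.9 CPM (median -0.50, -0.61 to -0.44, percentile 0). With the top 8% of doublet scores removed, these medians were -0.23 and -0.30. Glucose sensing genes had a median of -0.12, with FFAR1 2.68-fold lower, SLC2A1 2.64-fold higher and 14 of 17 within 2-fold. Beta cell factors had a median of -0.13, with MNX1 2.06-fold lower, and factors of other islet cells -0.51, with NEUROG3 and ETV1 2.34-fold and 2.20-fold lower. Enterochromaffin genes had a median of -0.07, with SLC6A4 lower. The sign was not kept by 3 of these lists, since the medians with the top 8% removed were 0.00 for glucose sensing genes, 0.04 for beta cell factors and 0.29 for enterochromaffin genes.

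The IRE1-XBP1 list was also lower in HET than in WT. Of its 30 genes 26 were lower, KDELR3 by 2.30-fold, and the median was -0.22 (-0.32 to -0.12, percentile 0.710), or -0.15 with clusters 14 to 18 weighing the same. ERN1 was 1.95-fold lower (1.61 to 2.36) and XBP1 1.18-fold (1.12 to 1.24). With those clusters weighing the same, their log2 ratios were -0.71 in place of -0.96 and -0.04 in place of -0.24. In the HET library's non-endocrine cells the median was -0.31 (-0.45 to -0.19), or -0.19 with non-endocrine clusters weighing the same, and gene by gene the endocrine-like ratios were higher than the non-endocrine ones by a median of 0.09 (0.03 to 0.18). ATF6 genes had a median of 0.01, all 19 within 2-fold. PERK-ATF4 genes had a median of 0.38 (0.11 to 0.58, percentile 100), with SLC7A11 2.53-fold and PSAT1 2.03-fold higher. With the top 8% of doublet scores removed this median was 0.11 (-0.03 to 0.26), and with doublets kept it was 0.03.

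KO and HET, compared directly over 3543 genes, had 11 genes at least 2-fold higher (17 with the top 8% of doublet scores removed) and 37 at least 2-fold lower in KO (22 with clusters weighing the same). Hormones had a median of -3.31, enterochromaffin genes 0.79 (0.50 to 1.26), exocytosis genes 0.36 (0.06 to 0.52) and IRE1-XBP1 genes -0.18 (-0.35 to -0.08, percentile 0). The IRE1-XBP1 ratios of KO to HET were lower in endocrine-like than in non-endocrine cells for 26 of 30 genes, by a median of -0.22 (-0.34 to -0.12). GCG, SST, PPY, IAPP, SLC30A8 and FFAR1 were lower in HET than in WT and lower again in KO, and CRH and TPH1 were higher in HET and higher again in KO. Over all kept cells, TPH1 was 19.0 CPM in WT, 15.2 CPM in HET and 57.4 CPM in KO. Other named genes did not follow the order of the genotypes. FOSB, SPP1, LTBP1, MLN, CDH6, TAGLN, FILIP1L and ANKRD1 were highest in HET, and PENK, STMN4, CALB2 and SMIM32 were lowest in HET. GHRL was higher in HET and higher again in KO in the class as a whole. It was lower than in WT in both with clusters weighing the same (log2 -0.54 in HET and -0.28 in KO). Cluster 15 set that mean. In clusters 14, 17 and 18 and in the low-UMI cluster 16, GHRL was higher than in WT in both libraries, with free RNA not subtracted. Among 3780 genes with at least 50 CPM in any of the 3 libraries, 57 were 2-fold higher in KO and 55 in HET than in WT, 24 of them in both, and 116 and 54 were 2-fold lower, 43 of them in both. Independent lists of these sizes would share 0.829 and 1.66, and libraries that differ by counting error alone shared 0 in 100 simulations. Neither figure allows for variation between differentiations or for doublets removed from WT alone, so an excess over them cannot be laid to genotype. The ratios correlated across genes at r = 0.71 against 0.41 simulated, with a covariance of 0.172 against 0.00136. Genes are not independent replicates, and both comparisons use the same WT library, which cannot be split. Part or all of the excess may come from that library, and the overlap was not counted with doublets treated alike.

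Beta-like cells formed cluster 18, with 177 WT, 54 HET and 46 KO cells (2.24%, 0.638% and 0.524% of kept cells, or 4.69%, 1.39% and 2.48% at resolution 0.5) and 2482536, 802839 and 627265 UMIs. INS was 12903 CPM in WT, 12372 CPM in HET and 4894 CPM in KO, 2.64-fold lower in KO (2.54 to 2.73). IAPP was 209 CPM in WT and had no count in the other libraries, at least 45.5-fold lower in KO and at least 55.7-fold lower in HET. Cluster 13, which was not called beta-like, had more of both in WT, at 16510 CPM of INS and 759 CPM of IAPP. FFAR1 and G6PC2 had no count in KO and were at least 11.9-fold and 7.37-fold lower there than in WT. The beta cell factors PDX1 (438 and 237 CPM) and NKX6-1 (288 and 174 CPM) lay within 2-fold in KO. PAX6 was 309, 249 and 445 CPM in WT, HET and KO. Hormone genes had 9 of 11 members at least 2-fold lower in KO and 8 of 11 in HET, with medians of -2.68 and -2.12, or -2.10 and -1.74 with IAPP and NPY at their bounds. Free RNA is not excluded from these counts, since PPY was 9.61 CPM in WT beta-like and 9.46 CPM in WT non-endocrine cells, and GCG was seen in 35.0% and 38.7% of them after thinning. Glucose sensing genes had 7 of 17 lower in KO and 3 of 18 in HET.

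Stress genes were also measured in beta-like cells. ERN1 was 24.7 CPM in WT, 20.01 CPM in HET and 24.5 CPM in KO, from 59, 16 and 16 counts, and its KO over WT ratio was 0.993 with a counting interval of 0.533 to 1.75. XBP1 was 301, 353 and 219 CPM. None of the 30 IRE1-XBP1 genes was 2-fold apart in KO or HET, and the medians were -0.29 (-0.48 to 0.01, percentile 1.53) and -0.07 (-0.28 to 0.10, percentile 47.7). PERK-ATF4 genes had medians of -0.32 in KO and 0.12 in HET, and ATF6 genes, which include ERO1B, a leading gene of the cluster, -0.20 and -0.05. Across all genes, 78 were 2-fold higher and 190 lower in KO, and 71 (45 with the top 8% of doublet scores removed) and 77 in HET. These counts come from few cells and include genes that define the cluster.

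Shares of cells with hormone UMIs were compared after each cell was thinned to 2000 UMIs, which left out 73 WT, 20 HET and 57 KO endocrine-like cells. INS was seen in 69.3% of WT, 62.0% of HET and 38.8% of KO endocrine-like cells, against 14.8%, 8.57% and 3.45% of non-endocrine cells. GCG was seen in 65.4%, 42.3% and 8.58% (non-endocrine 38.7%, 14.0% and 0.764%), SST in 29.2%, 17.0% and 4.02% (7.75%, 2.31% and 0.224%) and GHRL in 12.1%, 27.8% and 36.9% (0.610%, 2.96% and 4.06%). Before thinning, the median endocrine-like cell had 11942, 13111.5 and 12658 UMIs and the median non-endocrine cell 14343, 14036.5 and 15618. Shares without thinning were 87.8%, 81.1% and 58.8% for INS, 97.2%, 76.3% and 13.6% for GCG, 58.8%, 34.7% and 9.64% for SST and 30.9%, 56.8% and 64.5% for GHRL. With at least 5 UMIs in a thinned cell, which at most 0.516% of non-endocrine cells of any library reached for these genes, INS was seen in 52.8%, 45.7% and 18.8%, GCG in 32.9%, 26.5% and 4.57%, SST in 11.0%, 6.83% and 1.10% and GHRL in 2.71%, 11.5% and 19.1%.

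**Figure D4:**
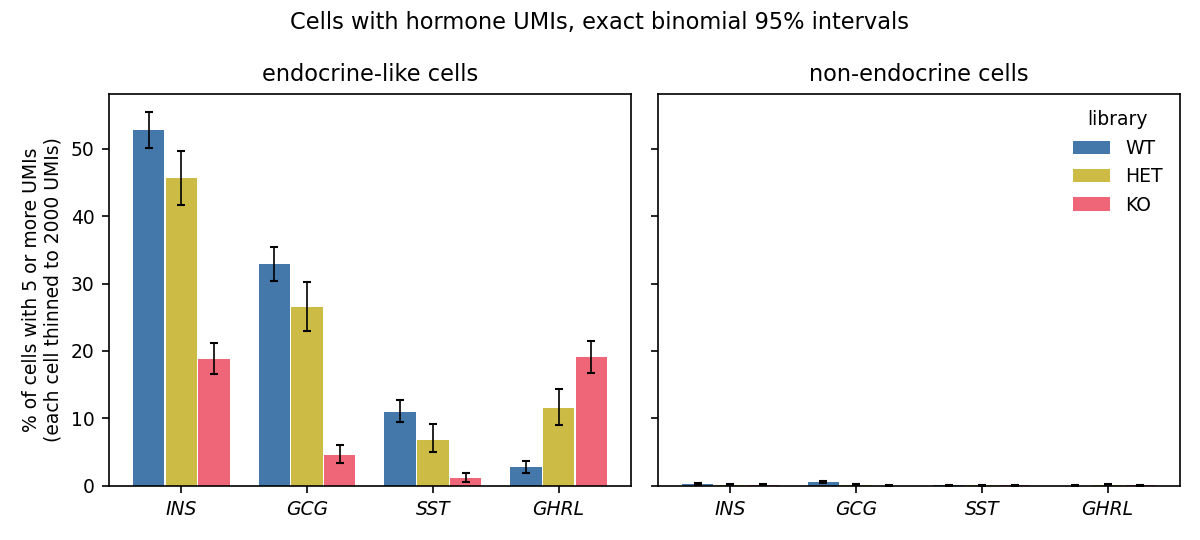
Percent of cells with at least 5 UMIs of INS, GCG, SST or GHRL (y axis) after thinning to 2000 UMIs, in endocrine-like and in non-endocrine cells of each library, with exact binomial 95% intervals that cover counting error only. In endocrine-like cells GCG is seen in 32.9% of WT and 4.57% of KO cells and GHRL in 2.71% and 19.1%, and no non-endocrine share is above 0.516%.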

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

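All tests below were chosen after seeing the data, that of transcript length before its own result was seen. The patterns weighed are the lower islet hormones in KO, the lower IRE1-XBP1 genes and the higher PERK-ATF4 genes.

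In the KO library's endocrine-like cells, 9 hormone genes were at least 2-fold lower than in WT while GHRL was higher. Free hormone RNA in the WT droplets does not carry the WT level, since over these 9 genes the median level in WT non-endocrine cells was 0.891% of that in endocrine-like cells (at most 4.31%, for NPY). With clusters 14 to 18 weighing the same, all 9 hormones were still at least 2-fold lower. Another mix of these clusters is therefore not the whole cause, but it bears on their size (log2 -1.19 in place of -2.44 for INS). That setting leaves out cluster 13, which had 2 KO cells, so it cannot weigh the near absence of this cluster from KO. Cluster 13 held 602195 of the 635956 endocrine-like WT counts of GCG and 54395 of the 58906 of PYY. Of SST it held 30631 of 119700. Within clusters, INS was near its WT level in KO in clusters 14 (1480 and 1413 CPM) and 15 (1989 and 2660 CPM) but lower in clusters 16 (7318 and 1450 CPM) and 18 (12903 and 4894 CPM), and PYY was near it in cluster 15 (376 and 358 CPM) but lower in clusters 14 (624 and 21.3 CPM) and 16 (1518 and 48.6 CPM), so how much of the change in these genes lies in the mix stays open. Removing doublets from WT alone is not the cause either, since 9 of 9 stayed 2-fold lower with the top 8% of doublet scores removed from each library. What stays open is the PAX6 genotype, which is untested, and any difference between single differentiations, which may give another set of endocrine cells.

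IRE1-XBP1 genes were lower in endocrine-like cells of both edited libraries (medians -0.44 in KO and -0.22 in HET). A shift of the whole library, reaching cells with little PAX6, may account for the HET value and for part or all of the KO value. The medians in non-endocrine cells were -0.29 (-0.37 to -0.16) in KO and -0.31 (-0.45 to -0.19) in HET. With non-endocrine clusters 1 to 11, which the libraries hold unequally, weighing the same, they were -0.25 (-0.35 to -0.09) and -0.19 (-0.38 to -0.12). Gene by gene, the endocrine-like ratios differed from the non-endocrine ones by a median of -0.17 (-0.24 to 0.02) in KO and 0.09 (0.03 to 0.18) in HET. Such a shift does not cover the KO and HET libraries' difference from each other. It was lower in endocrine-like than in non-endocrine cells by a median of -0.22 (-0.34 to -0.12), for 26 of 30 genes. This gap was not particular to the list, since it was -0.25 for ATF6 and -0.59 for PERK-ATF4 genes. It went the other way for exocytosis (0.30) and cholesterol synthesis genes (0.25). Transcript length does not account for the KO value, which was -0.37 (-0.61 to -0.15) after centring within bins of length, though the HET value was then -0.13 (-0.24 to -0.08). With endocrine-like clusters weighing the same, the medians were -0.27 in KO and -0.15 in HET. These were smaller in size but still negative, and inside the main intervals. That setting leaves out the largest endocrine-like cluster of WT, which was nearly absent from KO. It therefore cannot decide how much another mix of clusters contributes, and such a mix stays open. A difference between libraries or differentiations, an effect of PAX6 in endocrine cells and one earlier in differentiation also stay open and untested.

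PERK-ATF4 genes were higher in endocrine-like cells of both edited libraries (medians 0.26 in KO and 0.38 in HET). The doublet caller removed 294 WT cells that would otherwise be endocrine-like, with a median of 27556 UMIs, and none from HET or KO. With the top 8% of doublet scores removed from each library the medians were -0.23 (-0.36 to -0.10) in KO and 0.11 (-0.03 to 0.26) in HET, so unequal removal of doublets may explain the pattern. The medians were still positive, at 0.17 (0.07 to 0.45) and 0.34 (0.20 to 0.54), with clusters 14 to 18 weighing the same. That setting keeps the removal of doublets from WT alone and leaves out the largest endocrine-like cluster of WT. It therefore cannot decide whether another mix of clusters plays a part. A difference by genotype stays untested.

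Cluster 12, a non-endocrine cluster led by CXCL14, TFAP2B and GATA3, whose cells count in the non-endocrine class but which is compared on its own nowhere, held 8.31% of HET and 1.49% of KO kept cells and 0 of 7911 WT cells, which at 3 counts allows a WT share of up to 0.0379% (exact upper limit 0.0466%). HOXB2 moved opposite ways in HET against WT, with a log2 ratio of 1.42 in non-endocrine cells and -1.95 in endocrine-like cells, a difference that was not tested.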

How the results depend on the processing

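Each genotype had 1 library, so no alternative could leave out a replicate, and no result below has been set against variation between differentiations. No paired analysis was possible because the libraries are single and unpaired. Removing the top 8% of doublet scores, leaving out the low-UMI cluster, weighing clusters the same (also for the non-endocrine medians of 3 lists) and centring on transcript length were chosen after seeing the data, and the other settings were planned. Clusters weighing the same covers clusters 14 to 18, which had at least 20 cells in every library, and so leaves out cluster 13. Depth limits the beta-like values most, with 46 KO and 54 HET cells. A value was held to have moved when it left the main value's bootstrap interval (list medians), counting interval (single genes and shares) or a range of 1.5 times either way (counts of genes). Across the main values of the comparisons, 929 alternative values lay inside these bounds and 151 moved. Another 6 were list medians whose main interval excluded 0 and which changed sign. Among other values the numbers were 1051, 376 and 14. Wide intervals hide changes of sign, and counted without them 86 of 840 alternative list medians of endocrine-like cells and 85 of 516 of beta-like cells had the other sign, as did 1 of 9 of non-endocrine cells. Of 750 alternatives of 50 ratios of named genes, 14 had the other sign, 11 of them for ratios of at least 2-fold and 3 for PAX6 and INS with clusters weighing the same (INS 0.14 in HET/WT). The values of main comparisons that moved, and those that changed sign from an interval excluding 0 or a 2-fold ratio, are given next, for endocrine-like cells unless another class is named. A lower or absent minimum admits more genes and more low counts to the tally, and a higher number of UMIs required admits fewer cells. For the rest, the cause was not tested.

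With all kept cells in place of endocrine-like cells, genes 2-fold apart numbered 19 higher and 59 lower in KO/WT, 16 higher in HET/WT and 17 higher in KO/HET. Exocytosis had a list median of -0.51 in KO/WT, with 0.17 for cell cycle genes, -0.18 for genes kept low in islets, 0.37 for enterochromaffin genes, -0.33 for cholesterol synthesis, -0.61 for neuronal genes, -0.37 for intestinal markers and -0.14 for interferon genes, and the log2 ratio was -0.91 for PAX6 and -0.16 for THBS1. Hormones had a list median of -1.83 in HET/WT, with -0.84 for beta cell factors, -1.39 for granule genes, -1.06 for glucose sensing, -0.72 for exocytosis, -0.077 for PERK-ATF4 genes, -0.78 for enterochromaffin genes, 0.024 for immediate early genes, -1.27 for neuronal genes, -0.44 for liver markers, -0.34 for intestinal markers and -0.41 for interferon genes, and the log2 ratio was -1.69 for PAX6, -0.37 for ANKRD1 and -0.22 for TAGLN.

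With at least 3000 UMIs and at most 10% mitochondrial UMIs per cell, genes 2-fold apart numbered 85 higher in HET/WT. Exocytosis had a list median of -0.64 in HET/WT. Kept cells were divided with 16.1% in WT, 5.54% in HET and 8.09% in KO endocrine-like and 0.434% in HET beta-like.

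With at least 5 UMIs required, the shares of endocrine-like cells were 52.8% in WT, 45.7% in HET and 18.8% in KO for INS, 32.9% in WT, 26.5% in HET and 4.57% in KO for GCG, 11.0% in WT, 6.83% in HET and 1.1% in KO for SST and 2.71% in WT, 11.5% in HET and 19.1% in KO for GHRL.

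With cells thinned to 2000 UMIs, genes 2-fold apart numbered 19 higher in KO/HET. Immune markers had a list median of 0.22 in KO/WT, and the log2 ratio was -0.37 for PAX6. Exocytosis had a list median of -0.34 in HET/WT, with -0.40 for neuronal genes, and the log2 ratio was -0.51 for PAX6.

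With clusters weighing the same, genes 2-fold apart numbered 62 lower in KO/WT and 22 lower in KO/HET. ATF6 genes had a list median of -0.018 in KO/WT, with 0.59 for pluripotency markers, and the log2 ratio was 0.87 for PAX6, -0.64 for ACSL1 and -0.28 for GHRL. ATF6 genes had a list median of 0.15 in HET/WT, with -0.36 for neuronal genes, and the log2 ratio was 0.23 for PAX6 and -0.54 for GHRL. PERK-ATF4 genes had a list median of -0.033 in KO/WT (non-endocrine).

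With doublets kept, genes 2-fold apart numbered 17 higher and 34 lower in HET/WT and 32 higher in HET/WT (beta-like). PERK-ATF4 genes had a list median of -0.14 in KO/WT, with -0.32 for cell cycle genes, -0.47 for progenitor and duct genes and -0.39 for interferon genes, and the log2 ratio was -0.16 for PAX6. Granule genes had a list median of -0.29 in HET/WT, with -0.29 for exocytosis, 0.028 for PERK-ATF4 genes, 0.45 for cell cycle genes, 0.080 for immediate early genes, -0.38 for neuronal genes, -0.059 for liver markers and -0.38 for interferon genes, and the log2 ratio was -0.40 for PAX6 and -0.070 for TAGLN. Neuronal genes had a list median of 0.0075 in HET/WT (beta-like). Kept cells were divided with 20.5% in WT endocrine-like.

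With every cell weighing the same, granule genes had a list median of -0.37 in HET/WT, with -0.43 for exocytosis and -0.65 for acinar markers, and the log2 ratio was -0.53 for PAX6.

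With a minimum of 10 CPM, genes 2-fold apart numbered 204 higher and 402 lower in KO/WT, 202 higher and 209 lower in HET/WT, 62 higher and 145 lower in KO/HET, 434 higher and 735 lower in KO/WT (beta-like) and 473 higher and 442 lower in HET/WT (beta-like).

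Without a cell filter, genes 2-fold apart numbered 15 higher and 33 lower in HET/WT and 26 higher in HET/WT (beta-like). PERK-ATF4 genes had a list median of -0.14 in KO/WT, with -0.32 for cell cycle genes, -0.46 for progenitor and duct genes and -0.39 for interferon genes, and the log2 ratio was -0.16 for PAX6. Granule genes had a list median of -0.27 in HET/WT, with -0.28 for exocytosis, 0.038 for PERK-ATF4 genes, 0.49 for cell cycle genes, 0.086 for immediate early genes, -0.39 for neuronal genes, -0.074 for liver markers and -0.39 for interferon genes, and the log2 ratio was -0.40 for PAX6 and -0.069 for TAGLN. Neuronal genes had a list median of 0.013 in HET/WT (beta-like). Kept cells were divided with 19.6% in WT and 6.6% in HET endocrine-like and 2.82% in WT beta-like.

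With no expression minimum, genes 2-fold apart numbered 3248 higher and 3575 lower in KO/WT, 2992 higher and 2138 lower in HET/WT, 1582 higher and 2622 lower in KO/HET, 2462 higher and 1810 lower in KO/WT (beta-like) and 2480 higher and 1565 lower in HET/WT (beta-like).

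Without thinning, the shares of endocrine-like cells were 87.8% in WT, 81.1% in HET and 58.8% in KO for INS, 97.2% in WT, 76.3% in HET and 13.6% in KO for GCG, 58.8% in WT, 34.7% in HET and 9.64% in KO for SST and 30.9% in WT, 56.8% in HET and 64.5% in KO for GHRL.

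With plain CPM, ATF6 genes had a list median of -0.072 in KO/WT, and the log2 ratio was -0.32 for PAX6. Exocytosis had a list median of -0.44 in HET/WT.

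At resolution 0.5, kept cells were divided with 4.69% in WT, 1.39% in HET and 2.48% in KO beta-like.

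With the top 8% of doublet scores removed from each library, genes 2-fold apart numbered 24 higher in HET/WT, 17 higher in KO/HET and 45 higher in HET/WT (beta-like). PERK-ATF4 genes had a list median of -0.23 in KO/WT, with 0.035 for cell cycle genes, -0.10 for neuronal genes and -0.54 for interferon genes, and the log2 ratio was -0.21 for PAX6 and -0.21 for NRP2. Granule genes had a list median of -0.23 in HET/WT, with -0.30 for exocytosis, 0.11 for PERK-ATF4 genes, 0.75 for cell cycle genes and -0.34 for neuronal genes, and the log2 ratio was -0.33 for PAX6, -0.026 for ANKRD1 and -0.24 for TAGLN. Kept cells were divided with 6.69% in HET and 12.4% in KO endocrine-like.

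With totals that left out hormone and mitochondrial genes, genes 2-fold apart numbered 17 higher in KO/HET and 125 higher in KO/WT (beta-like). The KO/WT log2 ratio was -0.36 for PAX6.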

Other observations

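Hormones were seen together in single cells in proportions that differed between the libraries. Among endocrine-like cells thinned to 2000 UMIs, and with at least 5 UMIs required, INS and GCG were both present in 28.4% of WT cells (26.1 to 30.9), 23.3% of HET cells (20.004 to 26.9) and 3.29% of KO cells (2.31 to 4.52). None of INS, GCG, SST and GHRL was present in 39.5%, 42.3% and 66.03%. Ghrelin was found in 7 of 741 INS cells of WT, 17 of 274 of HET and 56 of 206 of KO (0.945%, 6.20% and 27.2%). GCG was found in 53.8%, 51.1% and 17.5% of the INS cells. Called doublets were removed from WT alone. After cells among the top 8% of doublet scores were also left out, a setting chosen after seeing the data, INS and GCG were both present in 25.3% of HET and 3.39% of KO cells, and ghrelin was found in 16 of 237 INS cells of HET and 51 of 189 of KO. Within cluster 15, GHRL was 17085 CPM in WT, 9490 CPM in HET and 9806 CPM in KO. It went the other way in cluster 14 (82.0, 145 and 256 CPM) and in the low-UMI cluster 16 (90.9, 1932 and 3970 CPM). Within cluster 14, TPH1 was 430 CPM in WT, 774 CPM in HET and 1129 CPM in KO.

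Other gene lists had these medians in endocrine-like cells, for KO and then HET against WT. Acinar markers, the digestive enzyme genes PRSS1, PRSS2 and CPA1, were lower (-2.51 and -1.45). Neuronal genes were lower (-0.35 and -0.56, or -0.10 and -0.34 with the top 8% of doublet scores removed from each library), with L1CAM at 13.2 CPM in WT, 4.67 CPM in HET and 3.87 CPM in KO, and endothelial markers were lower (-0.56 and -0.44, or -0.24 and -0.33 with the top 8% removed, 3 genes). Cholesterol synthesis genes were lower by less (-0.18 and -0.19, or -0.10 and -0.14 with the top 8% removed). Immune markers (3 genes) had medians of -0.12 and -0.60, and the KO value was 0.09 with the top 8% removed. Mitochondrially encoded genes were higher (0.39 and 0.44), with MT-ND6 at 161 CPM in WT and 323 CPM in KO, while nuclear-encoded oxidative phosphorylation genes were level (0.03 and 0.00). A higher mitochondrial share of UMIs can also come from damaged cells, and the median cell had 6.33% in WT, 8.44% in HET and 8.93% in KO. Cell cycle genes were higher (0.91 and 1.47), with TOP2A at 3.49 CPM in WT, 10.7 CPM in HET and 9.22 CPM in KO, but their medians were 0.03 and 0.75 with the top 8% removed. Immediate early genes (0.22 and 0.25), genes normally kept low in islets (0.33 and 0.44) and interferon genes (0.52 and 0.24) were also higher. The genes normally kept low had medians of -0.13 and 0.03, and the interferon genes -0.54 and -0.18, with the top 8% removed. Liver markers (0.16 and 0.66), intestinal markers (0.13 and 0.62), mesenchymal markers (0.02 and 0.37), pluripotency markers (0.07 and 0.23), progenitor and duct genes (-0.03 and 0.26), glycolysis and hypoxia genes (0.07 and 0.17) and apoptosis and p53 genes (-0.26 and 0.08) made up the rest. Their medians with the top 8% removed were -1.07 and 0.46 for liver markers, 0.02 and 0.10 for intestinal markers, -1.03 and -0.24 for mesenchymal markers, -0.15 and 0.32 for pluripotency markers, -0.40 and 0.00 for progenitor and duct genes, -0.17 and 0.01 for glycolysis and hypoxia genes, and -0.49 and 0.05 for apoptosis and p53 genes.

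Most kept cells were not endocrine-like, and their clusters were held unequally. Cluster 11, led by LYZ and LPL, held 10.5% of WT, 0.508% of HET and 1.61% of KO cells. Cluster 4, led by NOS1, DKK1 and NTS, held 3.05%, 19.1% and 4.37%. Cluster 2, led by MYOF, RBP4 and KRT7, held 4.79%, 4.92% and 18.2%, and cluster 3, led by PITX1 and DUOX2, 5.69%, 4.52% and 16.8%. Cluster 5, led by ANKRD1, TAGLN and NPPB, held 16.8%, 5.80% and 3.51%, and the proliferating cluster 10, led by TOP2A and MKI67, 4.02%, 6.32% and 5.00%. In non-endocrine cells PLCG2 was 570 CPM in WT, 138 CPM in HET and 163 CPM in KO, 4.13-fold lower in HET and 3.49-fold lower in KO. With 1 library per genotype, these shares describe single differentiations.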
